A study of Rattus norvegicus with 6 samples.

How the data were processed

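Gene expression was measured in primary astrocyte cultures from rat spinal cord with the Affymetrix Rat Genome 230 2.0 array, on which a gene is read by one or more probe sets. Total RNA, 5 ug per array, was taken from confluent monolayers kept for 24 hours in supplemented L15 medium and labelled with a one-cycle protocol, per the labels and the series' design text. The 6 arrays fall into 2 groups of 3 by their titles: NonTG, cultures without the transgene, and SOD1-G93A, cultures carrying human superoxide dismutase 1 with the G93A substitution. Each group has a replicate A, B and C.

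The deposited values are intensity values, one per probe set and array on a linear scale, made by the authors with MAS5 in GCOS 1.4, per the submitters' processing notes. The series' design text speaks of GC-RMA normalization in ArrayAssist 4.0 and of log values, but the values analysed here are linear, and the mean signal after trimming 2% at each end lay between 500.16 and 500.17 on all 6 arrays, which is what MAS5 scaling to a common target gives. The median signal per array ranged from 128.85 to 136.28. The table held 31099 probe sets, 57 of which were controls and were left out of the tests. Of the 31042 others, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none; 20758 of those with 1 symbol were matched to the current rat gene table by Entrez identifier, and no symbol needed an update. No gene was named from a probe set with several symbols, and a probe set without a symbol is unnamed here.

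The log2 of each value was taken with no pseudocount and no further normalization. Detection calls were not used here, so probe sets whose mean log2 value over the 6 arrays was at or below the 40th percentile, a signal of 66.7, were left out as dim. This left 18625 probe sets, 14633 of them with 1 symbol, for 10473 genes. SOD1-G93A was compared with NonTG in limma 3.58.1 under R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Differences are SOD1-G93A minus NonTG on the log2 scale. The number of arrays limits the precision: the median standard error of a difference was 0.16, and the 95% confidence interval lay within 2-fold in both directions for 90.8% of the probe sets and within 1.5-fold for 63.6%. A permutation test of 3 arrays against 3 cannot give a p below 0.1. No label says that the 3 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

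For gene lists, each gene was represented by its brightest tested probe set. In total 45 lists, 36 of gene functions and 9 of cell type markers, were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 44 lists that had at least 5 measured members. Camera with a correlation estimated per list and limma's fry were run beside it. The result of 1 function list is not reported here, though it is part of the counts of lists. For plots and exact permutation tests, the value of a list on an array was the median over its members of the log2 signal minus that gene's mean over the 6 arrays, so the difference of list values can depart slightly from the median of the gene differences. The genes named in the text were drawn from a set fixed by rule, which began with Sod1. It held in each direction 12 genes by size of difference among those past the threshold with no overlap between groups. Where fewer passed, it was filled with the smallest unadjusted p among the others without overlap. It also held the 4 members with the smallest p of each list described and the 3 brightest members of each cell type list. For some lists only part of these members is given. Genes named for the letters were the 12 with the smallest p in the test of the letters, with clock genes and the members of lists that an explanation needed; these were chosen later. The lists, the tests of genes and of lists, this rule and most alternatives were fixed before the data were examined. Alternatives added later were the test of the letters, the block with an estimated correlation, the pairing on spike-in controls, the clock genes, the oligodendrocyte list without Mbp and Cnksr3 or without probe sets for several transcripts, and a floor on the Dcn signals. The second simulation and several tests of explanations, named where they are given, were also chosen later.

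The letters A, B and C occur in both groups. Whether they pair the arrays was checked from each array's deviations from its group mean over the tested probe sets: the correlation between same-letter arrays of the 2 groups was 0.30 for A, 0.25 for B and 0.20 for C, against -0.28 to 0.025 for different letters. All 6 arrays had their highest cross-group correlation with the array of the same letter. Deviations cancel within a group, so positive same-letter correlations push the different-letter ones down, and these are no independent baseline. Arrays can be paired across the groups in only a few ways, and no chance level was computed. The pairing is thus read from the data, within that limit, and not from a label that states a shared litter, day or batch. A fit with the letter as a block is given beside each count that it moves by more than 1.5 times.

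Alternatives covered quantile normalization and median centring of the arrays, pseudocounts of 16 and of the 20th percentile of all values (23.1), no filter and a filter at the 60th percentile, variance models without the intensity trend and with robust estimation, array weights, the letter as a block, leaving out each array in turn, leaving out probe sets ending in _s_at or _x_at, which may detect several transcripts, other thresholds, ordinary linear-model statistics, and other forms of the list test. The fit was tested on simulated data: 200 of 18625 probe sets were changed in each of 20 draws for the comparison of SOD1-G93A with NonTG. The variances were first set to limma's posterior value of each probe set. With independent arrays the fit then recovered 73.4% of 2-fold and 96.9% of 4-fold changes, with 12.4 false calls on average among 182.6, or 6.79%, above the nominal 5%. With the letter effects measured here added, it recovered 58.4% and 88.8% without a block (0.102% false calls), and 85.4% and 98.2% with the letter as a block (9.67% false calls). After these false calls were seen, a second simulation was added that drew the variances from limma's fitted prior, where the model's assumption holds by construction. There it recovered 61.5% and 91% with independent arrays (4.78% false calls), and with letter effects 51.6% and 87% without a block (0.681%) and 71.3% and 93.4% with one (4.88%). Adjusted p-values of the fit with a block may therefore be too small by an amount that depends on the true variances. The letter effects added were the measured letter means of every probe set, which still hold noise between arrays and so are too large. Recovery and false calls without a block may thus be too low in these draws, and the gain from the block overstated. In all these simulations, covering 10473 genes, a shift of 0.3 in the proteasome list was called in 20 of 20 draws, with the preset and with an estimated correlation. Beside the letter effects, noise was drawn independently for each gene, while the median correlation estimated within the lists measured here was 0.14. The draws therefore do not show how often a list whose members vary together would be called.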

Results

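The data are 6 arrays of cultured rat spinal cord astrocytes, 3 from cultures without a transgene (NonTG) and 3 from cultures carrying the human SOD1-G93A transgene, a mutant form of superoxide dismutase 1 linked to familial amyotrophic lateral sclerosis. Signals are the authors' MAS5 intensities, and differences are on the log2 scale with 3 arrays per group.

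Markers of astrocytes and of other cell types were measured in both groups. Signals of different probe sets cannot be compared as amounts, so they do not give the share of a cell type. The brightest of the 16 measured astrocyte markers was Fabp7, a fatty acid binding protein of glial cells, at a mean log2 signal of 14.47 in NonTG and 14.38 in SOD1-G93A. Next were Gja1, a gap junction protein, at 13.96 and 14.01, and Aqp4, a water channel, at 13.92 and 14.04. Gfap, the astrocyte intermediate filament, was at 14.02 and 13.91. Microglia and macrophage markers were near the lower limit of measurement: 3 of the 20 on the array were above the filter, too few to test. The brightest, Laptm5, a lysosomal membrane protein of blood cells, was at 7.15 and 6.96, followed by Fcer1g and Lyz2. Collagen genes of the fibroblast and meningeal list were bright in both groups, with Col1a2 at 14.45 and 14.32, Col3a1 at 13.80 and 13.58 and Postn, a matrix protein, at 13.59 and 13.22.

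Sod1, the endogenous rat gene for the enzyme that the transgene encodes in its human form, was read by 1 probe set (1367641_at). Its signals on the NonTG arrays were 8982, 8855 and 9430, and on the SOD1-G93A arrays 9781, 10860 and 10510, a difference of 0.19 (SE 0.069, 95% interval 0.036 to 0.35), or 1.14-fold. All 3 SOD1-G93A arrays lay above all 3 NonTG arrays, but limma's adjusted p was 0.9997, and 0.762 to 0.9999 over the alternatives. The probe set was designed for the rat transcript, and whether it also detects the human one was not tested. It therefore does not check the presence of the human transgene.

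No probe set passed the adjusted threshold in limma, and the genes that follow are described by their values as not passing. The largest of the 24 named differences was that of Dcn (1370956_at), the collagen-binding proteoglycan decorin, 2.52 higher in SOD1-G93A (SE 0.32, 95% interval 1.79 to 3.25). Its signals were 59.1, 92.3 and 63.9 in NonTG against 666.7, 283.2 and 348.6 in SOD1-G93A. Also among the higher ones were Aldh1a2 (1368003_at), the retinaldehyde dehydrogenase that makes retinoic acid, by 1.15 (SE 0.23) and Stra6 (1385476_x_at), a membrane receptor for retinol uptake, by 1.22 (SE 0.34). Among the lower ones was Mcl1 (1372520_at), a member of the Bcl2 family that protects cells from apoptosis. Its difference was -0.40 (SE 0.078), with NonTG signals of 3626 to 4104 and SOD1-G93A signals of 2944 to 3014. Ptbp3 (1382005_at), an RNA-binding protein that regulates splicing, had a difference of -1.21 (SE 0.23) and Tfe3 (1388967_at), a transcription factor of lysosomal genes, one of -0.63 (SE 0.11). In their lower group Dcn, Stra6, Vezf1 and Isg20l2 had 2 or 3 of 3 signals under 66.7, the level of the dim filter, so the sizes of their differences are uncertain. With a pseudocount of 23.1 they were 2.19, 0.92, -1.02 and -0.68.

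Limma's smallest adjusted p was 0.4004, for Dcn and an unnamed probe set (1385919_at) with a difference of -0.66 (SE 0.091). All other named genes had 0.9997. With the letter as a block the smallest was 0.1506, for Dcn and Ptbp3. Adjusted over the list alone, Dcn (0.000440) and Aldh1a2 (0.00600) passed in limma among the 18 measured fibroblast and meningeal markers, Dcn (0.00135) among the 55 measured genes of extracellular matrix and adhesion, and Mcl1 (0.0143) among the 24 of apoptosis. These were the only calls of that kind in the 45 lists, and no correction was made across the lists.

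The other genes named as higher in all 3 SOD1-G93A arrays had differences of 0.37 to 1.42. They included Nckap5l, a protein of microtubules and centrosomes (1.42, SE 0.32), and Prrt1, a membrane protein associated with AMPA receptors (0.54, SE 0.16). Phf14, a chromatin protein with PHD fingers (0.53, SE 0.16), Srsf11, a splicing factor (0.48, SE 0.14), and Klf5, a zinc finger transcription factor (0.46, SE 0.14), came next. Abca2, a lipid transporter of lysosomal membranes, differed by 0.45 (SE 0.14) and Fbxo28, a subunit of a ubiquitin ligase, by 0.42 (SE 0.13). The last were Asrgl1, an asparaginase, at 0.39 (SE 0.11) and Timm17b, a part of the import channel of the inner mitochondrial membrane, at 0.37 (SE 0.11). The other genes named as lower began with Vezf1, a zinc finger transcription factor (-1.35, SE 0.36), and Ppp1r3f, a glycogen-targeting subunit of a protein phosphatase (-0.91, SE 0.22). They also held Kank3, a regulator of actin (-0.87, SE 0.23), and Isg20l2, an exonuclease of ribosomal RNA processing (-0.87, SE 0.25). Mplkip differed by -0.70 (SE 0.18), Pgam5, a mitochondrial phosphatase, by -0.49 (SE 0.13), and Il11ra1, a receptor chain for interleukin 11, by -0.43 (SE 0.12). Cyp1b1, a cytochrome enzyme that metabolizes steroids and retinoids (-0.38, SE 0.10), and Itprid2, which binds inositol trisphosphate receptors (-0.38, SE 0.091), completed the set.

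Other probe sets of the same genes did not always follow. A second Nckap5l probe set differed by 0.27 (SE 0.29), a second one of Tfe3 by -0.13 (SE 0.20), and 2 of Mplkip by -0.0047 and -0.22. A second Mcl1 probe set differed by 0.028 (SE 0.097), 3 further ones of Vezf1 by 0.020 to 0.088, one of Srsf11 by 0.022 (SE 0.090) and one of Stra6 by 0.14 (SE 0.28). Those of Phf14 ranged from -0.51 to 0.42 and those of Asrgl1 from -0.037 to 0.41. A second Ptbp3 probe set was lower by 0.71 in SOD1-G93A (a difference of -0.71, SE 0.26), and those of Klf5 were higher by 0.33 and 0.39.

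**Figure D1:**
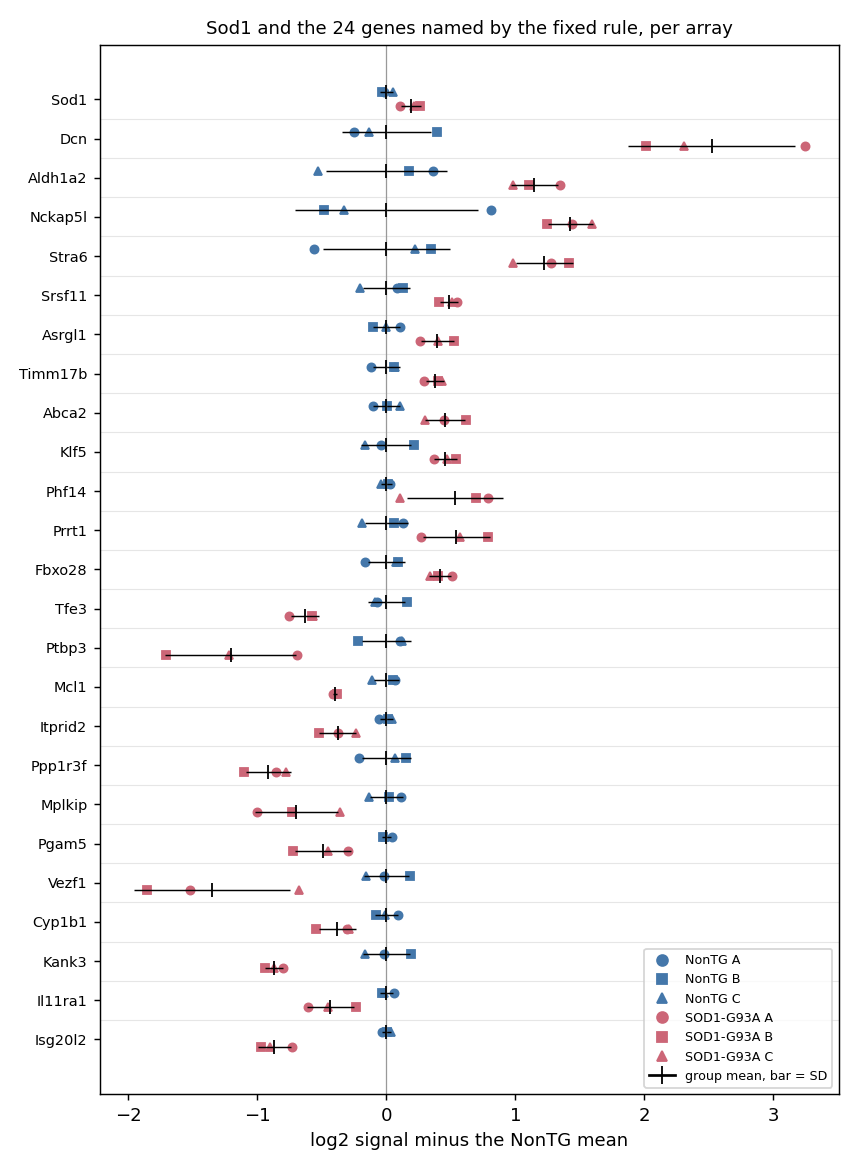
Log2 signal minus the NonTG mean (x axis) of Sod1 and the 24 named genes (y axis), one point per array, with shapes for the replicate letters, colours for the groups, and each group's mean and SD (n = 3) as a bar. Groups do not overlap for any of these genes, which the rule required of the 24 but not of Sod1, and the SOD1-G93A mean of Dcn lies 2.52 above that of NonTG.

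Across all 18625 probe sets, limma called 0 at an adjusted p of 0.05 and 0 at 0.10. There were 474 with an unadjusted p below 0.05, 250 higher and 224 lower in SOD1-G93A, where 931 would be counted with no effect and no pairing of the arrays. With the letter as a block, 1090 had an unadjusted p below 0.05 and again 0 passed after adjustment. The unadjusted count was 822 without NonTG A and 1183 without SOD1-G93A A. The 3 arrays of one group lay wholly above or below those of the other for 1398 probe sets, or 7.51%, where 10% would be so with no effect and no pairing of the arrays, and 58 probe sets differed by 1 or more.

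The mean Pearson correlation of arrays over probe sets was 0.974 within groups and 0.976 between them, and also 0.974 between groups without the pairs that share a letter. The highest correlation of all pairs was 0.985, between NonTG A and SOD1-G93A A. The ratio of 3' to 5' signals, which reflects RNA integrity, was for Gapdh 0.988 ± 0.030 (SD, n = 3) in NonTG and 1.002 ± 0.0062 in SOD1-G93A (exact permutation p = 0.7), and for actin 1.16 ± 0.030 and 1.117 ± 0.022 (exact permutation p = 0.2). The actin ratio was lower in SOD1-G93A within each of the 3 letters.

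**Figure D2:**
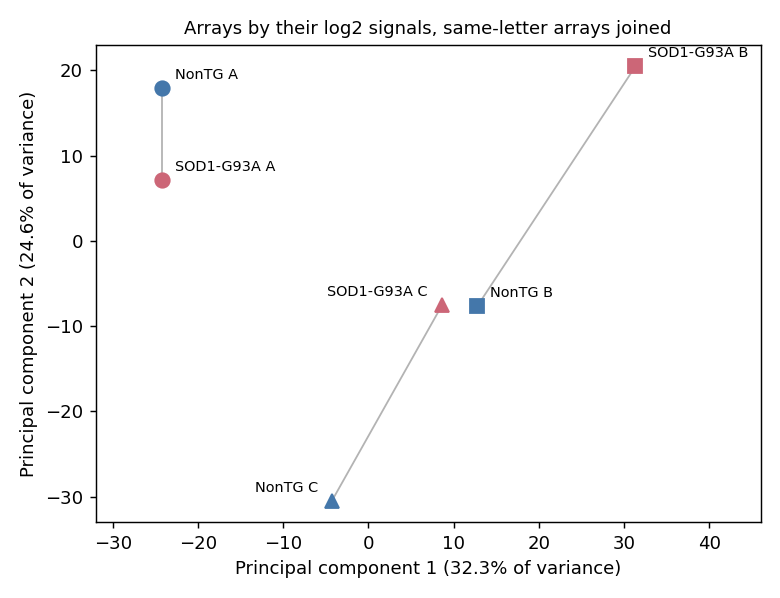
Principal components 1 and 2 (axes, with 32.3% and 24.6% of the variance) of the log2 signals of the 6 arrays over the tested probe sets, with colours for the groups, shapes for the letters, and a line joining the arrays that share a letter. NonTG A and SOD1-G93A A both lie at -24.24 on component 1, and neither component parts the groups.

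Among the cell type lists, markers of the oligodendrocyte lineage were higher in SOD1-G93A. Of the 10 measured members 9 were higher, with a median difference of 0.33, and the list's value lay between 0.15 and 0.29 on the SOD1-G93A arrays and between -0.14 and -0.025 on the NonTG arrays (exact permutation p = 0.1, the smallest possible). The members with the smallest p were Cnksr3, a scaffold protein (0.40, SE 0.13), Ugt8, which makes the myelin lipid galactosylceramide (0.72, SE 0.27), Mag, a myelin adhesion protein (0.63, SE 0.27), and Lhfpl3 (0.24, SE 0.12). The NonTG signals of Ugt8 (82.9, 58.3 and 62.2) lay in part under 66.7, the level of the dim filter, so the size of its difference is uncertain. Mbp, myelin basic protein, differed by 0.78 (SE 0.46), Olig1, a transcription factor of the lineage, by 0.13 (SE 0.15), and Cnp, a bright myelin enzyme, by -0.18 (SE 0.10). Camera's adjusted p was 0.000281 with the preset correlation and 0.586 with an estimated one, and 0.0504 with the stricter filter on dim probe sets (6.29e-05 to 0.736 over all alternatives).

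Pericyte and smooth muscle markers were lower, all 11 of 11 measured, with a median difference of -0.26. They included Lmod1, an actin regulator of smooth muscle (-0.58, SE 0.21), and Rgs5, a signalling protein of pericytes (-0.90, SE 0.62). The brightest were Tagln, Myl9 and Acta2: Acta2, smooth muscle actin, differed by -0.38 (SE 0.28), Myl9, a myosin light chain, by -0.30 (SE 0.36), and Tagln, an actin-binding protein, by -0.14 (SE 0.087). Camera's adjusted p was 0.00736 with the preset correlation and 0.798 with an estimated one. Without SOD1-G93A B the median was -0.028 and the call ended (adjusted p of 0.981 in camera), and without SOD1-G93A A the median was -0.44. The call also ended without NonTG A (adjusted p = 0.0528), without NonTG C (0.156, median -0.17), with array weights (0.0632), with no filter (0.118) and with the stricter filter (0.179).

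Cytokine, chemokine and NF-kB target genes were lower in SOD1-G93A for 25 of 32 measured members, with a median difference of -0.22. The 4 with the smallest p were Il1r1, the receptor for interleukin 1 (-0.34, SE 0.11), Ccl7, a chemokine for monocytes (-1.29, SE 0.42), Cxcl1, a chemokine for neutrophils (-0.99, SE 0.36), and Icam1, an adhesion molecule (-0.25, SE 0.10). Camera's adjusted p was 2.89e-05 with the preset correlation and 0.798 with an estimated one. Without NonTG B the median was -0.076 and the adjusted p 0.286, and without NonTG A the median was -0.35. Over all alternatives the adjusted p ranged from 5.15e-12 to 0.867.

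Ribosomal protein genes were lower by a small and even amount, 22 of 23 measured, with a median of -0.11. Rps3 (-0.19, SE 0.061), Rps6 (-0.17, SE 0.072) and Rps23 (-0.15, SE 0.066) of the small subunit and Rpl35 (-0.12, SE 0.062) of the large one had the smallest p. Camera's adjusted p was 2.07e-08 with the preset correlation and 0.798 with an estimated one. After quantile normalization the median was -0.031 and the call was lost (adjusted p = 0.0804, with 1.51e-11 to 0.867 over all alternatives), and without SOD1-G93A A the median was -0.072. Within the letters A, B and C the list value differed by -0.099, -0.12 and -0.11, though the groups overlap when the letters are ignored.

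Cell cycle genes were higher for 37 of 43 measured members, with a median of 0.12. Examples were Aurkb (0.44, SE 0.16) and Plk1 (0.29, SE 0.18), both mitotic kinases, Pttg1, the securin that holds sister chromatids together until anaphase (0.21, SE 0.12), and Ccne1, the cyclin of entry into S phase (0.46, SE 0.29). Camera's adjusted p was 0.00696 with the preset correlation and 0.827 with an estimated one, and 0.0632 with array weights. The median was -0.017 without NonTG C, 0.049 without NonTG B, 0.059 without SOD1-G93A A and 0.069 without SOD1-G93A B, none of which passed the test (adjusted p = 0.782, 0.286, 0.421 and 0.127). It was 0.35 without NonTG A and 0.26 without SOD1-G93A C, which did pass.

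Apoptosis genes were lower for 16 of 24 measured members, with a median of -0.093. They included, beside Mcl1, Casp12, a caspase of the endoplasmic reticulum (-0.58, SE 0.17), Apaf1, the scaffold of the apoptosome (-0.29, SE 0.14), and Endog, a mitochondrial nuclease (-0.29, SE 0.16). The list thus held genes that protect from cell death and genes that promote it. Camera's adjusted p was 0.0126 with the preset correlation and 0.586 with an estimated one, 0.0643 without NonTG B, 0.104 without NonTG C (median -0.021) and 0.11 with the mean over all probe sets of a gene. Without NonTG A the median was -0.14.

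**Figure D3:**
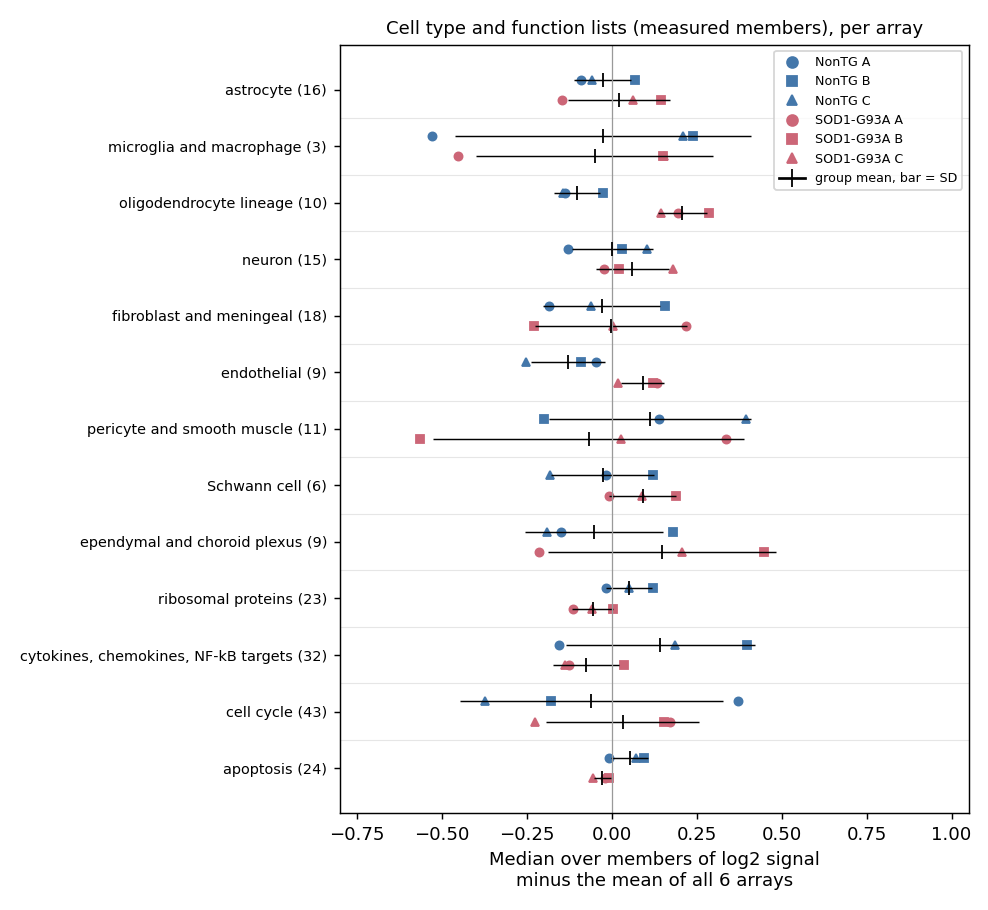
Value of each cell type list and of 4 function lists that passed the preset-correlation test (y axis, measured members in brackets) on each array, as the median over members of the log2 signal minus the gene's mean over 6 arrays (x axis); colours are the groups, shapes the letters, bars the mean and SD (n = 3). The SOD1-G93A arrays lie above all NonTG arrays for the oligodendrocyte lineage (difference 0.31) and the endothelial list (0.22) and overlap with them in the other lists drawn.

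With the preset correlation 7 of the 44 lists tested passed camera's threshold, 2 higher and 5 lower in SOD1-G93A. With an estimated correlation (smallest adjusted p = 0.586) or by fry in its directional form (0.590), 0 passed. Within the letters A, B and C the oligodendrocyte list value differed by 0.33, 0.31 and 0.29 and that of apoptosis by -0.0095, -0.10 and -0.13. Those of 3 other lists had another sign under A: pericyte and smooth muscle markers (0.19, -0.37 and -0.37), cytokines (0.028, -0.36 and -0.33) and the cell cycle (-0.20, 0.33 and 0.15). With the letter as a block 14 passed, and 0 when the correlation was estimated as well. The count was 13 without NonTG A, 16 without SOD1-G93A A and 14 without SOD1-G93A C. The smallest adjusted p in camera among the 37 lists that did not pass was 0.0519, for NADPH oxidase and nitric oxide genes (median -0.22), which passed with the letter as a block (0.00756) but not when the correlation was estimated as well (0.736). None of the 37 had a larger median difference in either direction.

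The antioxidant and energy lists gave no call. Targets of Nrf2, the transcription factor of the antioxidant response, had a median difference of -0.0078 over 26 measured members, with a mean of 0.026 that the test follows (camera's adjusted p = 0.648). Among them Slc7a11, the cystine transporter that feeds glutathione synthesis, was higher in all 3 SOD1-G93A arrays by 0.49 (SE 0.17). Gstp1, a glutathione transferase, differed by 0.13 (SE 0.073), Blvrb, a biliverdin reductase, by 0.23 (SE 0.13) and Txnrd1, thioredoxin reductase, by 0.14 (SE 0.087). The median was 0.017 over 14 mitochondrial antioxidant enzymes, while their mean of -0.018 and the test pointed lower (adjusted p = 0.908). Sod2, the mitochondrial superoxide dismutase, differed by -0.33 (SE 0.19) and Msrb2 by -0.25 (SE 0.25), while Idh2 (0.18, SE 0.14) and Oxr1 (0.11, SE 0.11) were higher. Oxidative phosphorylation had a median of -0.0082 over 57 members (adjusted p = 0.601), with Atp5pb, a subunit of ATP synthase, at -0.16 (SE 0.089).

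Astrocyte lists likewise stayed below the threshold. Astrocyte markers had a median of 0.074 over 16 members (camera's adjusted p = 0.532). Agt, angiotensinogen, differed by 0.41 (SE 0.18), Slc1a2, the main glutamate transporter of astrocytes, by 0.47 (SE 0.23), Fgfr3, a growth factor receptor, by -0.20 (SE 0.11) and Gfap by -0.12 (SE 0.070). Astrocyte reactivity genes had a median of -0.085 over 30 members (adjusted p = 0.128). Sphk1, a sphingosine kinase (-0.76, SE 0.24), Serpina3n, a protease inhibitor (-0.97, SE 0.38), and Cd44, a hyaluronan receptor (-0.27, SE 0.11), were on the lower side. The SOD1-G93A signals of Serpina3n (63.5, 36.1 and 66.2) were all under 66.7, the level of the dim filter, so the size of its difference is uncertain. On the higher side was Sparcl1, a secreted matrix protein that promotes synapse formation (0.60, SE 0.22). Genes of glutamate and neurotransmitter handling had a median of 0.080 over 21 members (adjusted p = 0.244), with Gria2, an AMPA receptor subunit, at -0.35 (SE 0.22) and Abat, which breaks down GABA, at 0.25 (SE 0.17).

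The other cell type lists gave no call. The fibroblast and meningeal list had a median of -0.13 and a mean of 0.13, and camera placed it higher (adjusted p = 0.934). Fry's mixed form, which counts changes in either direction, gave this list an unadjusted p of 0.000164. That form was not adjusted over the lists. Dcn, Aldh1a2 and Fbln1, a matrix glycoprotein (0.41, SE 0.15), were higher, and 11 of 18 members were lower, with Col1a2 at -0.12 (SE 0.065). Endothelial markers had a median of 0.096 over 9 members (adjusted p = 0.197). Slco1a4, an organic anion transporter, differed by 0.64 (SE 0.26), Slc2a1, the glucose transporter, by 0.29 (SE 0.12) and Kdr, a receptor for vascular growth factor, by 0.65 (SE 0.41). Eng, also among the brightest, differed by -0.37 (SE 0.44), and 4 of the 9 members were lower. Neuron markers had a median of -0.019 over 15 members, with a mean of 0.011 that the test follows (adjusted p = 0.371). Reln, a secreted guidance protein, differed by 0.44 (SE 0.15), Stmn2, a microtubule regulator, by 0.19 (SE 0.10) and Uchl1, the brightest, by -0.077 (SE 0.13). The medians were 0.10 over 6 Schwann cell markers (adjusted p = 0.532), of which Pmp22 was the brightest, and 0.054 over 9 ependymal and choroid plexus markers (adjusted p = 0.324), of which Pltp was the brightest.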

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

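The block with an estimated correlation, and the oligodendrocyte list without Mbp and Cnksr3 (median 0.25, adjusted p = 0.01003 in camera), were chosen after seeing the data; the others here were planned. Limma gave 0 probe sets past the adjusted threshold in all 17 alternative fits and by ordinary linear-model statistics, and 151 at an unadjusted p below 0.05 with at least 1.5-fold. The count of 474 with an unadjusted p below 0.05 became 999 with no filter (more probe sets tested), 283 with the stricter filter (fewer tested), 852 with array weights, 1090 with the replicate block, and 340 to 1183 when each array was left out; beyond the filters the cause was not tested. The 7 gene lists past the threshold became 14 with the replicate block, 0 with an estimated correlation and 0 by fry in its directional form. They became 0 with the block and an estimated correlation, and 5 to 16 when each array was left out. The cell cycle median turned from 0.12 to -0.017 without NonTG C and ranged from -0.017 to 0.35 over the arrays left out; the cause was not tested. Of 141 values of the 7 lists under alternatives, 102 kept their direction and call, 38 kept only their direction and 1 reversed. All 399 values of the named genes kept their direction and none passed (smallest adjusted p = 0.1506, limma). The rule required groups without overlap in these same data, so leaving out an array could not turn a direction. Settings that change only the variance model or the filter leave the difference itself unchanged. The kept directions are therefore little support for these genes. The block changed no call of a gene. Robust estimation was not run for the lists, which camera has no option for. Signal near the filter level limits what dim genes such as Dcn and Stra6 can show: the stricter filter leaves out Dcn.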

Other observations

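The tests of the cell type share, of the kind of probe set, of the other fibroblast markers and of the splits of the arrays, and the comparison of the letters, were chosen after the result was seen, as was the signal level that separates dim fibroblast markers. More probe sets differed between the replicate letters than between the genotypes. In limma's model of letter and genotype, 195 of 18625 probe sets differed between letters at an adjusted p below 0.05, and 2897 at an unadjusted one, where 931 would with no effect. Lcn2, the iron-binding lipocalin of reactive astrocytes, had signals of 1186 and 962.3 on the 2 arrays with letter A, 6413 and 3999 on those with B, and 2603 and 2508 on those with C. Mt2A, a metallothionein, had 4404 and 4067 with A, 10000 and 9183 with B, and 6317 and 6516 with C. Col4a1, a basement membrane collagen, went the other way, with 6432 and 6116 under A, 2832 and 2803 under B, and 3728 and 3658 under C. Cemip, a hyaluronan-degrading protein, Akap12, a kinase anchoring protein, Fhl2 and Eln were also highest under A, Naprt was highest under B and Slc14a2 and Crym under C, and Nxph1, a neurexin ligand, had 605 and 547.3 under C against 87.0 and 116.5 under A.

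Of the lists, pericyte and smooth muscle markers spread most between letters, with deviations of 0.22 for A, -0.45 for B and 0.13 for C, followed by the cell cycle (0.27, -0.0039 and -0.31), complement (-0.26, 0.24 and 0.032) and the 3 microglia and macrophage markers (-0.31, 0.16 and 0.18). Antigen presentation (-0.15, 0.24 and -0.027) and the interferon response (-0.12, 0.21 and -0.012) were also highest under B.

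Arrays that share a letter deviated together in the pairing check, for which no chance level was computed. Intensity-dependent scaling is argued against, since the lowest same-letter correlation stayed at 0.1858 after quantile normalization. A labelling or hybridization batch stays open: over 42 bacterial spike-in probe sets the mean same-letter correlation was 0.2022 (0.067 for A, 0.24 for B and 0.30 for C) against -0.10 for different letters, whose range of -0.44 to 0.31 includes all 3. Here too the centring on group means pushes the different-letter values down, so they are no independent baseline. A candidate explanation for letter A is a different circadian phase at RNA isolation: Dbp, a clock output gene, had 455.1 and 508.4 under A against 1062 to 1334 under B and C, and the median deviation of 7 other output genes was -0.531 (SE 0.249), 6 of them lower under A with Hlf higher, while 3 antiphase genes had a median of 0.18 (SE 0.24). The SEs of these medians are over genes read on the same arrays and do not measure the spread between arrays. A different phase under A says nothing about why B and C deviate, and shared animals, litters or culture days remain untested.

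The oligodendrocyte lineage list was higher in all 3 SOD1-G93A arrays, though its call was lost with an estimated correlation. A lower share of astrocytes that raises all other cell types alike is argued against, within a limit. The list's difference exceeded the mean of 6 other cell type lists by 0.2361 (SE 0.070), while astrocyte markers differed by 0.047 (SE 0.10). The limit is that the oligodendrocyte list was singled out for its difference, which favours such an excess and which the SE leaves out. Endothelial (0.22) and ependymal (0.20) lists were also higher and pericyte markers lower (-0.18), so a shift that raises only some types stays open. Probe sets that may detect several transcripts read 2 of the 10 members, Mag and Mbp. The planned filter removed no member. Without all probe sets of that kind the median was 0.2433 with 7 of 9 higher, though Mbp then differed by -0.21. That median is the value of Lhfpl3, whose probe set was not changed. A change in 2 of 10 members could hardly lower it, so the test cannot decide whether such probe sets matter. Of the 10 splits of the 6 arrays only the real one, 1 split, gave a difference as large (0.31, highest other 0.1966), and 10 splits are too few to exclude chance. The list was singled out after the result was seen, which favours the real split. Groups were separate in 2 of the 44 lists tested, where 10% would be so with no effect and no pairing of the arrays. A larger share of oligodendrocyte-lineage cells and a change within cells both remain open as hypotheses.

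Dcn was higher in all 3 SOD1-G93A arrays. More fibroblast or meningeal cells in general are argued against, though 6 of the 17 other measured markers were higher, Aldh1a2 (1.15) and Fbln1 (0.41) in all 3 arrays: the median of the 17 other measured markers was -0.1335 (SE 0.16), and that of the 11 with a mean log2 signal under 10 was -0.038 (SE 0.23). The SEs of these medians are over markers and do not measure the spread between arrays. The low NonTG signal alone does not carry the Dcn difference. With a pseudocount of 23.1 the difference was 2.1908, and with signals under 66.7 raised to that level, a test chosen later, 2.44. Leaving out each array gave 2.1587 to 2.78. A difference in Dcn itself between these cultures remains a hypothesis. A shift in only some fibroblast or meningeal cells, with Aldh1a2 and Fbln1 higher beside Dcn, was not tested and stays open too. Either may follow the transgene, the animals or the dishes, and limma's adjusted p for Dcn was 0.4004 for 3 arrays against 3.

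The 10 splits of the arrays are too few for a share below 0.05 in any count. The real split gave 474 probe sets with an unadjusted p below 0.05, 8 of the 10 gave as many, and the highest other gave 2247. That split put NonTG A, NonTG C and SOD1-G93A A together. It kept the letter A pair whole and, on the other side, the B pair, so the structure by letter may enter its count. The 3 other splits that part all 3 pairs gave 208, 286 and 841, and with the letter as a block 370, 501 and 2009 in the same order against 1090 for the real one, the largest with the letter A pair turned round. A block removes a shift shared by a letter, so such a shift does not account for 2009. Within A, many probe sets thus differed between the groups in the opposite sense to B and C, which limits what can be read as a difference of genotype. All 10 splits gave 0 probe sets after adjustment (highest other 0). For the gene lists 7 of 10 splits gave as many as the 7 of the real one (highest other 24).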
